A study of Mus musculus with 4 samples.

How the data were processed

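The data were single-cell RNA sequencing of healthy adult mouse prostates, deposited as 4 libraries made by droplet capture of transcript 3' ends. Per the labels, each library came from 1 mouse, and the lobes named AP, VP and DLP were digested together for 1 h. The labels give 10 mg/mL cold protease without sorting for 2 libraries, the same protease with a CD326- magnetic sort for 1, and 1.5 mg/mL collagenase I without sorting for 1. CD326 is the protein encoded by Epcam, so the sorted library is labelled as depleted of epithelial cells. Per the labels, the cold-protease libraries used version 2 of the kit and the collagenase library version 3, and 17400 cells were to be loaded per library. Enzyme, kit version and mouse therefore changed together in the collagenase library.

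The deposited files hold raw UMI counts per gene and cell barcode, where a UMI tags 1 captured RNA molecule, beside lists of gene identifiers, gene symbols and barcodes. Per the submitters' processing notes, counts were made with Cell Ranger 4.0.0 on the mouse build mm10. The gene annotation release used for counting is not given in the sources used here. Gene positions were taken from the GENCODE M 21 annotation of the same build, which covered 32158 of 32285 features by identifier, and 78 symbols shared by several identifiers were kept apart. Raw reads, unfiltered barcodes, protein data and spatial data were not analysed here.

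The files held 61234 barcodes and 357532135 UMIs. Barcodes were kept with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs. The gene minimum applied to 677, 65, 479 and 680 barcodes in cold protease 1, cold protease 2, the CD326-depleted library and the collagenase library, and the mitochondrial limit applied to 623, 96, 1010 and 1729. Some barcodes failed both, and 6266, 27286, 16436 and 7193 passed. Doublets were scored with Scrublet at an expected rate of 10%. The automatic threshold failed in the collagenase library, so a fixed score of 0.25 was applied to all libraries, a choice made after the scores were seen. It removed 260, 3379, 1111 and 311 barcodes and left 52120 cells.

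Counts were scaled to 10000 per cell and logged, 2000 variable genes were ranked within libraries, and 30 principal components and 20 neighbours were used for Leiden clustering at resolution 1. Epcam and the 227 genes of the 14 fixed lists took no part in clustering. Clusters were named from markers of 22 cell types fixed before the data were examined, by the mean log2 ratio of each marker to the lower quartile over clusters of the same library. At least 3 markers had to be 2-fold up, and clusters were left unnamed where a second lineage reached 50% of the score, where another type led the top 10 genes, or where shallow cells had no leading marker. This naming rule was revised after the clusters were seen, while the markers were not. It named 38 of 42 clusters in 11 classes, written here as X-like cells, and left 2.96, 1.75, 3.29 and 27.6% of cells unnamed in the 4 libraries. Fibroblast-like cells were clustered again at resolution 0.5 after centring each library. Shares carry exact 95% binomial (Clopper-Pearson) intervals, which cover counting error only and not spread between mice.

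UMIs were summed per library and class with at least 20 cells. Sums were compared with edgeR 4.0.16 quasi-likelihood fits after TMM scaling and filterByExpr, with Benjamini-Hochberg adjustment over all tested genes at 0.05. All adjusted p-values in the text come from these fits unless DESeq2 is named. The standard error after a log2 fold change, also drawn in the figures, is approximate. It is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. Adjustment over the genes of the 14 lists together was run as well and is called adjusted over the list alone. In the group comparisons only the 2 unsorted cold-protease mice gave replicate spread, leaving 1 residual degree of freedom, and each lone library was taken to vary as that pair did. The prior degrees of freedom of edgeR were infinite in basal-like and fibroblast-like cells, so that all genes there took the same trend of spread and the p-values rest on it. Class contrasts used a block for library, so each class was compared with another class of the same mouse. Changes with no count on 1 side are given as lower bounds from a floor of 3 counts, and changes with 1 to 3 counts as a ratio with its exact counting interval.

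Lists, contrasts and alternatives were fixed before the data were examined. The alternatives fixed in this way were, for the cells, a stricter filter (1000 UMIs, 500 genes), at most 10% mitochondrial UMIs, no doublet removal, Leiden resolution 2, clustering of each library alone and thinning to 1000 UMIs per cell. For the tests they were RLE scaling, DESeq2, no count filter, only the 3 libraries of a group comparison, no library block, subclusters without centring or at resolution 1, and leaving out 1 library at a time. Without either cold-protease mouse a group comparison has no residual degree of freedom, so those alternatives gave values and no test. 4 further alternatives were chosen after seeing the data: cluster 9 counted as distal luminal-like (in the shares and in the collagenase comparison) and fibroblast-like cells without the 3 subclusters led by neuronal, mesothelial and glial genes (in the collagenase and smooth muscle comparisons).

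Genes to name were set by rule: per class of a group comparison the 5 largest rises and 5 largest falls that passed, with a mean log2 CPM of at least 5 and the same direction against both cold-protease mice, leaving out predicted, ribosomal protein and mitochondrial genes. In class contrasts up to 3 genes per list and direction were named, and a fixed set of genes, Epcam among them, always. List genes named in the group comparisons beyond this rule, and genes of the smaller classes, were chosen after their values were seen.

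Counts with changes of known size were simulated at the fitted dispersion and passed through the same fits. Of changes of log2 2, 54.6% were recovered for collagenase in distal luminal-like cells, 0% in basal-like cells and 1.02% in fibroblast-like cells. For the library labelled CD326-depleted these shares were 60, 14.1 and 2.11%. In class contrasts 57.1% (fibroblast against smooth muscle), 91.5% (basal), 92.7% (proximal luminal), 96.6, 96.7 and 85.6% (fibroblast subclusters 0, 1 and 3) were recovered. A gene that did not pass in a group comparison was thus not shown to be unchanged.

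Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1.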

Results

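Single-cell RNA was measured in prostates of healthy adult mice as UMI counts per gene and cell, where each UMI tags 1 captured RNA molecule. The 4 libraries, each of 1 mouse per the labels, were 2 unsorted cold-protease digests (cold protease 1 and 2), 1 cold-protease digest labelled CD326-depleted and 1 unsorted collagenase I digest. After filtering, 6006, 23907, 15325 and 6882 cells remained, in that order, from deposited totals of 39475315, 125132345, 125429640 and 67494835 UMIs. The kept cells had medians of 3807, 4005, 3915 and 3671 UMIs. The comparisons ask how sorting and the enzyme bear on the cell types and genes recovered, and how prostate cell types differ from each other within a mouse.

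Epcam encodes the epithelial adhesion protein CD326 (ENSMUSG00000045394, mm10 chromosome 17, 87635979 to 87651129). Its RNA gives an indirect check of the depletion label, since the sort acts on the protein. Epcam RNA was not lower in the library labelled CD326-depleted: it stood at 278 CPM (UMIs scaled to a common total, 95% exact interval 275 to 281), against 263 (258 to 268) in cold protease 1 and 252 in cold protease 2. Cells with an Epcam UMI made up 53% of that library, against 54.3% and 54.1% in the unsorted cold-protease libraries and 55.2% with collagenase. In fibroblast-like cells, which should lack the gene, the shares were 3.9, 16, 9.64 and 15.6%, at median depths of 1972, 1399, 2313 and 6933 UMIs. With every cell thinned to 1000 UMIs, 20.1, 20.8, 19.7 and 31.8% of all cells had an Epcam UMI, against 2.16, 10.8, 3.07 and 3.89% of fibroblast-like cells. Within distal luminal-like cells Epcam did not pass the test for the library labelled CD326-depleted (log2 fold change 0.36 ± 0.35, adjusted p = 0.573), nor did it in basal-like cells (0.22 ± 0.66, adjusted p = 1). The label and the measured Epcam RNA are therefore at odds, and the name below is that of the label.

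**Figure D1:**
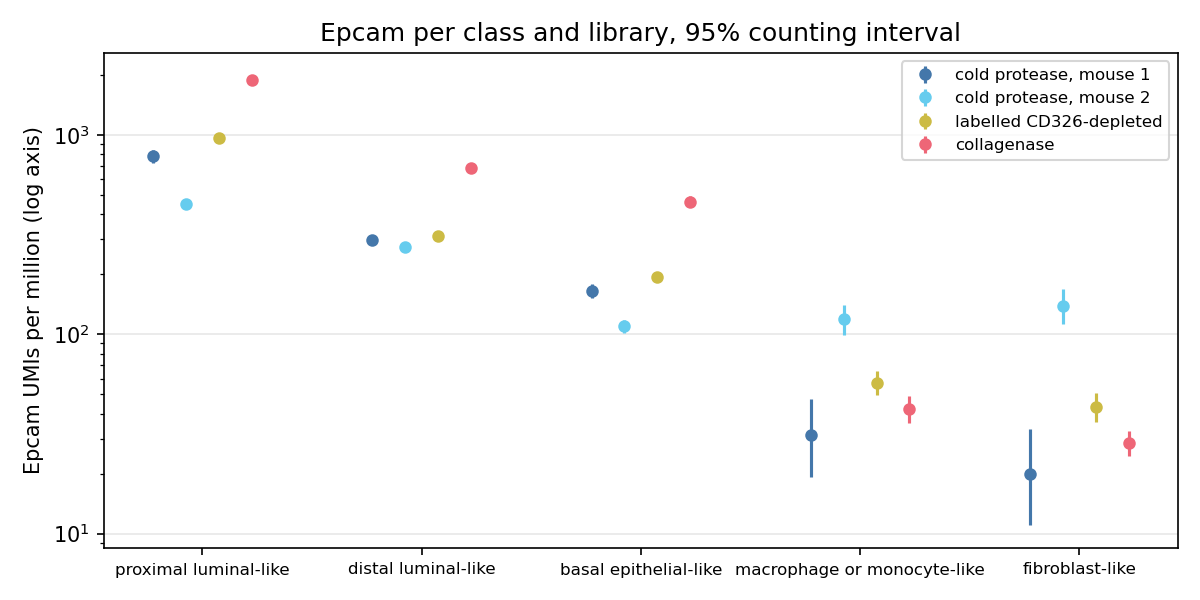
Epcam RNA in 5 cell classes of each library, in CPM of the UMIs summed per class (log axis), with 95% counting intervals. Distal luminal-like cells stand at 313 in the library labelled CD326-depleted, beside 298 and 273 in the unsorted cold-protease libraries and 684 with collagenase.

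Epithelial cells made up most cells of every cold-protease library, and fibroblast-like and macrophage-like cells took larger shares after collagenase than in unsorted cold protease. Epithelial-like cells, named by keratin and secretory markers, were 83.4% (82.4 to 84.3) of cold protease 1, 92.5% (92.1 to 92.8) of cold protease 2, 77.8% (77.1 to 78.4) of the library labelled CD326-depleted and 46.2% (45 to 47.4) of the collagenase library. Basal-like cells, which sit under the luminal layer, were 39.7% (38.9 to 40.5) of the library labelled CD326-depleted, above the 17.6 ± 5.94% of the unsorted cold-protease pair (mean ± SD, n = 2). Distal luminal-like cells, the main secretory type, were 35.3% there and 61.5 ± 11.4% in the pair, so that basal-like cells per distal luminal-like cell came to 1.13 against 0.408 and 0.193. Fibroblast-like cells were 14% (13.2 to 14.8) of the collagenase library, 7.99% (7.56 to 8.43) of the library labelled CD326-depleted and 3.77 ± 2.51% of the pair. Macrophage-like cells were 8.06% with collagenase, 7.37% in the library labelled CD326-depleted and 3.18 ± 1.02% in the pair. Unnamed cluster 19, with macrophage or monocyte as its best match, is not in these shares. It held 150, 191, 429 and 23 cells of the 4 libraries, so the shares do not rank collagenase above the library labelled CD326-depleted. Basal-like cells were 4.52% (4.04 to 5.04) of the collagenase library, but 9.33% with the stricter cell filter and 7.21% with each library clustered alone. Seminal vesicle epithelial-like cells made up 4.47 ± 0.742% of the pair, 0.574% of the library labelled CD326-depleted and 0.0291% of the collagenase library, where they were 2 cells. With 1 mouse per sorted or collagenase library, differences between mice cannot be told from those of the protocol.

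Haemoglobin genes and transcripts that overlap ribosomal RNA led a large unnamed cluster of the collagenase library. That cluster 9 held 27.2% of its cells and 0.45, 0.0125 and 0.3% of the other libraries, at a median of 978 UMIs. It was led by the haemoglobin genes Hbb-bs and Hba-a2 and by Gm26917, Lars2 and Gm42418. Ren1, C1rb and Fgl1 were also among its leading genes, and Ren1 and C1rb led distal luminal-like cluster 10 too. Markers of 2 lineages left it unnamed, with scores of 5.42 for erythroid and 3.11 for distal luminal. Unnamed collagenase cells (1873 of 1896 in cluster 9) held Pbsn at 9420 and Tgm4 at 14400 CPM. Distal luminal-like collagenase cells held 9310 and 16500. Sbp, Msmb, Spink1 and Defb50 were lower in the unnamed cells. Counted as distal luminal-like, an alternative chosen after seeing the data, cluster 9 raised the epithelial share of the collagenase library from 46.2 to 73.4%. Some classes parted by library in this joint clustering, which used no batch correction. T or NK-like, B or plasma-like, endothelial-like, ionocyte-like and smooth muscle-like cells were each named from 1 cluster with cells of all 4 libraries. Ionocyte-like cells had only 1 collagenase cell, and smooth muscle-like cells only 7 of cold protease 1. The basal-like cells of the collagenase library lay to 95.8% in cluster 31, led by Hbegf, Dnajb1, Arc and Hspb1, while those of cold protease 2 lay to 98.5% in cluster 3. Distal luminal-like cells of the collagenase library lay to 52.6% in cluster 10, where the stress gene Atf3 led, and its macrophage-like cells to 57.5% in cluster 28, where the inflammatory genes Cxcl2, Il1b and Cd83 led. Cluster 14, led by the division genes Top2a, Cenpf and Mki67, held 6.25% of distal luminal-like cells in cold protease 2 and 0.281, 0.333 and 0.352% in the others.

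**Figure D2:**
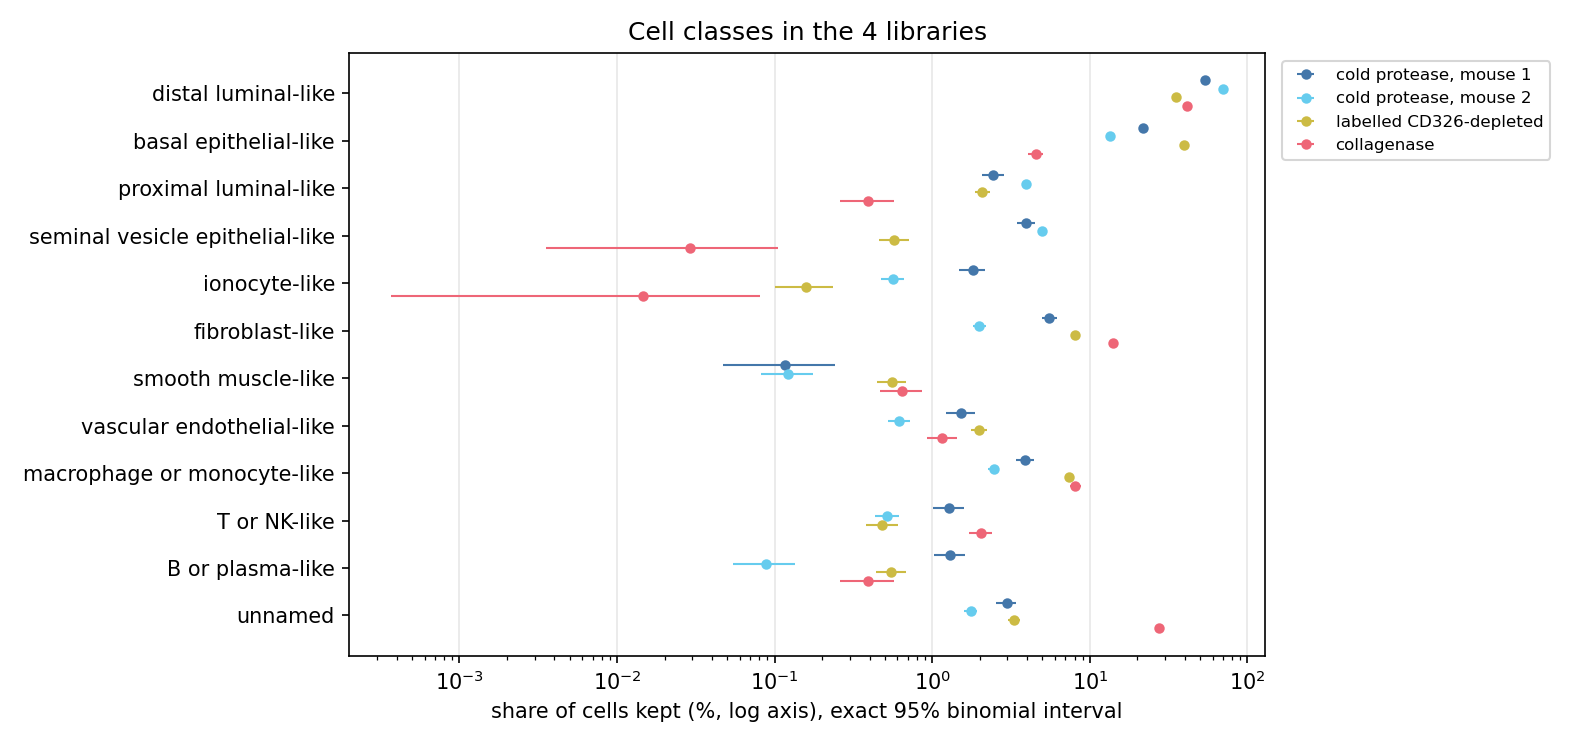
Share of kept cells per cell class (percent, log axis) in each of the 4 libraries, with exact 95% intervals for counting error. Distal luminal-like cells make up 35.3% of the library labelled CD326-depleted, and fibroblast-like cells run from 1.99% to 14%.

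Early-response transcription factors, which cells switch on within minutes of a stimulus, were far higher in the collagenase library than in unsorted cold protease in distal luminal-like, basal-like and fibroblast-like cells. In distal luminal-like cells Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273) rose from 4.46 and 3.86 CPM in the cold-protease mice to 764, Jun from 39.6 and 19.3 to 1620, and Atf3 from 12.1 and 9.03 to 1310. The list of immediate-early genes had 17 of 18 members higher and 0 lower in these cells. Adjusted over the list alone these were 17 and 0, and the median log2 fold change was 4.3. The collagenase library was also the only one made with the newer kit and from its own mouse, so enzyme, kit and mouse are not separated. Of 15468 genes tested in distal luminal-like cells 1115 passed, 635 higher and 480 lower.

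The AP-1 members Fosb, Fos and Jun, the related factor Atf3 and the zinc-finger factors Egr1 and Egr2 had the 6 largest early-response changes in distal luminal-like cells. Fosb rose by log2 10.38 ± 0.43 (adjusted p = 2.66e-06), Egr2 by 7.95 ± 0.40 (8.12e-06), Fos by 7.53 ± 0.38 (8.12e-06). Atf3 rose by 6.96 ± 0.41 (1.29e-05), Egr1 by 6.85 ± 0.37 (9.25e-06) and Jun by 5.79 ± 0.47 (8.74e-05). The phosphatase gene Dusp1, which damps MAP kinase signals, rose by 4.42 ± 0.29, and Zfp36, which speeds decay of inflammatory RNA, by 2.04 ± 0.27. In basal-like cells 17 of 18 immediate-early genes were higher and 0 lower, the same adjusted over the list alone, with a median of 4.59. Atf3 rose by 9.40 ± 0.73 (adjusted p = 5.02e-34), Fos by 7.57 ± 0.76 (5.57e-20), Egr1 by 5.99 ± 0.66 (1.08e-16) and Jun by 5.33 ± 0.67 (7.53e-13) there. Fosb had 3 counts in the cold-protease mice and 2183 with collagenase, a ratio of 3240 (1110 to 15700). In fibroblast-like cells 16 of 18 were higher and 0 lower, 17 and 0 adjusted over the list alone, with a median of 4.76. Atf3 rose there by 8.72 ± 1.00 (adjusted p = 3.04e-14), Fos by 6.35 ± 0.88 (3.5e-10), Egr1 by 5.76 ± 0.86 (7e-09) and the growth regulator Myc by 2.55 ± 0.65 (0.00477), while Jund, at 2.18 ± 0.80, did not pass. These fibroblast calls were lost in 2 alternatives: without doublet removal and with each library clustered alone edgeR passed 0 genes of any list, with 822 and 862 of all genes at unadjusted p < 0.05. Atf3 stood there at 8.44 ± 0.96 and 8.13 ± 0.92 without passing, and DESeq2 in the fit above passed 14 of the 18.

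**Figure D3:**
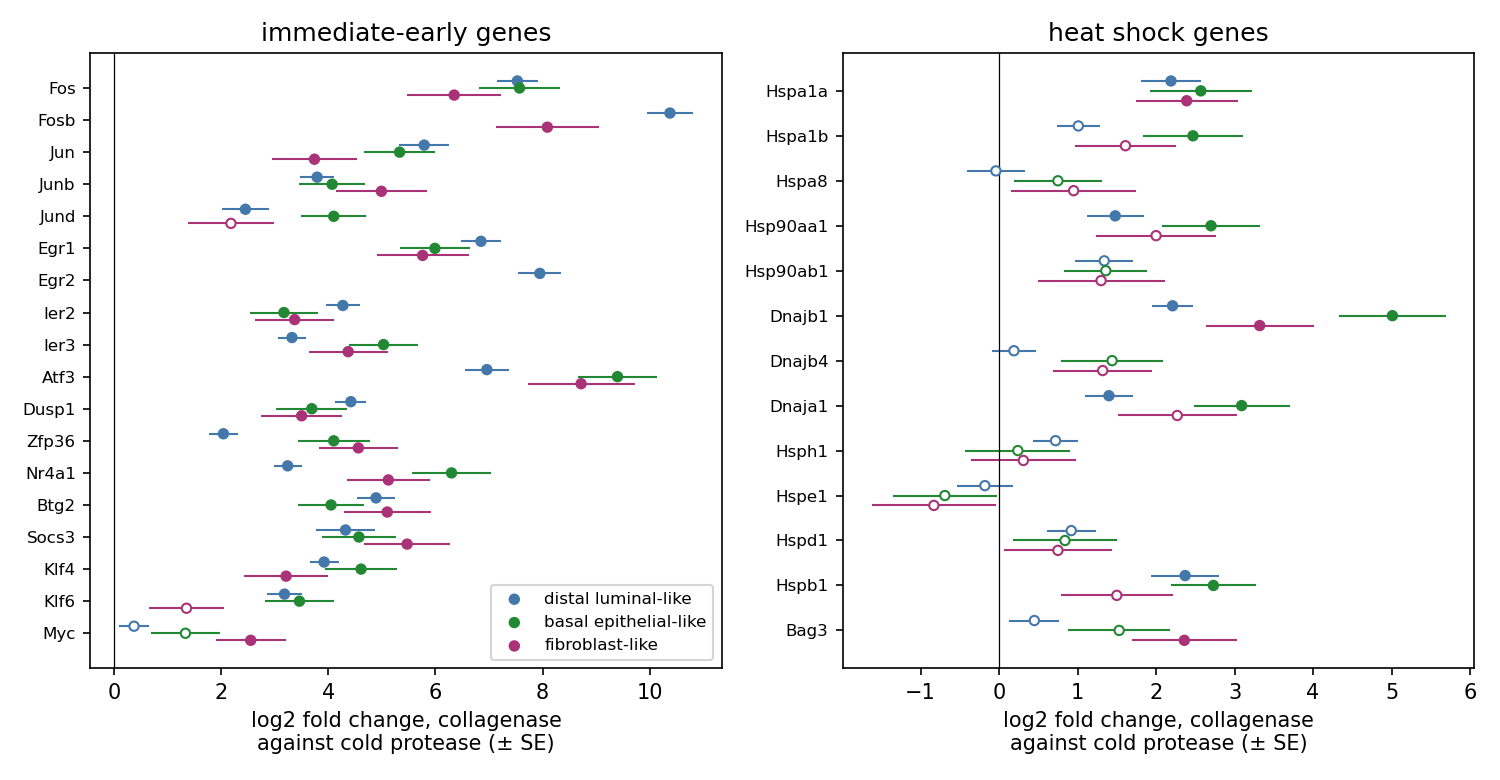
Log2 fold change of immediate-early and heat-shock genes, collagenase against unsorted cold protease, in distal luminal-like, basal-like and fibroblast-like cells, with standard errors as bars, open circles for genes that did not pass, and genes with at most 3 counts on 1 side not drawn. Atf3 lies at 6.96, 9.40 and 8.72 in the 3 classes.

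Some heat-shock genes, whose products refold damaged proteins, rose as well. In distal luminal-like cells 5 of 13 were higher (8 adjusted over the list alone), in basal-like cells 6 (7) and in fibroblast-like cells 3 (5), none lower. The co-chaperone gene Dnajb1 rose by log2 2.21 ± 0.26 (adjusted p = 0.00114), 5.01 ± 0.68 (5.2e-11) and 3.32 ± 0.69 (0.000132) in the 3 classes. The inducible HSP70 gene Hspa1a rose by 2.19 ± 0.38 (0.0104), 2.57 ± 0.65 (0.00306) and 2.39 ± 0.65 (0.0117). Some chemokine genes, which call immune cells, rose in each class. The list gave 5 higher and 2 lower of 19 in distal luminal-like cells (7 and 4 adjusted over the list alone), 5 and 0 of 15 in basal-like (5 and 1) and 6 and 0 of 17 in fibroblast-like cells (7 and 0). The interferon-induced Cxcl10 rose by 5.38 ± 0.54 (0.000372), 5.13 ± 0.70 (6.87e-11) and 7.13 ± 0.88 (6.94e-13). The neutrophil attractant Cxcl1 rose by 4.11 in distal luminal-like and 6.18 ± 0.76 in basal-like cells. In fibroblast-like cells the cytokine gene Il6, without a count in the cold-protease mice, was at least 32.3-fold higher, and the monocyte attractant Ccl7 rose by 4.99 ± 0.76 (1.85e-08). Cxcl17, a mucosal chemokine, fell by 2.21 in distal luminal-like cells (0.0136). The heat-shock and chemokine calls in fibroblast-like cells were lost in the same 2 alternatives, and DESeq2 passed 1 and 4 genes of these lists in the fit above.

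Hormone and developmental signalling genes changed in few members. No gene of steroid receptors and metabolism passed in any of the 3 classes, of 11, 9 and 9 tested, by edgeR or adjusted over the list alone. With the stricter cell filter Srd5a2, which makes dihydrotestosterone and stood at 0.02 ± 0.68, passed in fibroblast-like cells at −4.41 ± 0.90 (adjusted p = 8.43e-05). The oestrogen receptor Esr1 stood at −0.68, −0.03 and −0.29 and did not pass. Of 10 androgen-responsive genes 3 rose and 1 fell in distal luminal-like cells (3 and 2 adjusted over the list alone), among them Ndrg1 up by 3.26 and the glucocorticoid-induced Fkbp5 down by 1.43. Of them 2 rose in basal-like cells (5 alone) and 0 passed in fibroblast-like cells (1 higher and 1 lower alone). Wnt genes gave 1 higher of 15 in distal luminal-like cells, Wnt4 by 1.12 (2 and 1 adjusted over the list alone), and 0 of 12 and 18 in the others (1 higher alone in basal-like cells). FGF, IGF, HGF and EGF genes gave 2 higher and 1 lower of 22 (3 and 1 alone), with the EGF-receptor ligand Areg up by 4.45 and Igfbp5 down by 1.38. They gave 1 of 17 (2 alone) and 0 of 21 (2 alone) in the other classes. BMP and TGF-beta genes gave 0 of 12 (1 higher and 1 lower alone), 2 of 10 (2 alone), the activin antagonist Fst up by 4.19 and Bmp2 by 2.86 in basal-like cells, and 0 of 14 (1 alone). Hedgehog genes gave 0 of 6, 4 and 7, and Notch genes 1 lower of 10, the target Hey1 down by 1.80 (1 higher and 2 lower alone), then 0 of 8 and 7. DESeq2 also passed 0 wherever edgeR did in these lists, and it passed 0 of the Wnt genes in distal luminal-like cells and of the BMP and growth factor genes in basal-like cells, where edgeR passed 1, 2 and 1. Unadjusted p < 0.05 was reached there by 4, 1 and 0 steroid genes in distal luminal-like, basal-like and fibroblast-like cells and by 0 hedgehog genes in all 3. It was reached by 4 BMP and TGF-beta genes in distal luminal-like, 1 Wnt and 2 Notch genes in basal-like, and 4 androgen-responsive, 3 Wnt, 2 growth factor, 1 BMP or TGF-beta and 1 Notch genes in fibroblast-like cells.

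Matrix and immune-effector genes had few members past the threshold. Of basement membrane genes 2 rose of 17 in distal luminal-like cells (3 adjusted over the list alone), the laminin chain Lamb3 by 1.99 and Col18a1 by 1.60. In fibroblast-like cells 0 of 17 passed. Fibrillar and elastic matrix genes gave 1 higher and 1 lower of 21 (2 and 1 alone), Sparc up by 2.52 and Col6a3 down by 2.55, then 0 of 14 (1 alone) and 0 of 21 (1 alone). Complement genes gave 0 of 12, 11 and 12 (2 higher alone in distal luminal-like and 1 lower alone in fibroblast-like cells), with C3 at 0.30, 0.85 and 0.69. Interferon-response genes gave 1 of 13, 0 of 11 and 1 of 11 (1, 0 and 3 alone), Isg15 up by 1.69 in distal luminal-like and 2.44 ± 0.66 in fibroblast-like cells. Where edgeR passed 0 in these lists DESeq2 did too, and DESeq2 passed 0 where edgeR passed 2 basement membrane genes in distal luminal-like cells and 1 interferon gene in fibroblast-like cells. At unadjusted p < 0.05 there were then 3, 0 and 1 complement genes in the 3 classes, 2 fibrillar matrix and 1 interferon genes in basal-like cells, and 2 basement membrane and 3 fibrillar matrix genes in fibroblast-like cells. Over all genes 602 of 12278 passed in basal-like cells, 463 higher and 139 lower. In fibroblast-like cells 394 of 11772 passed, 272 higher and 122 lower. The fibroblast count was not stable: it was 0 without doublet removal (822 at unadjusted p < 0.05) and 0 with each library clustered alone (862), and 131 with DESeq2. The prior degrees of freedom of edgeR were infinite for the 394 genes, so that all genes shared 1 trend of spread, and 5.84 and 6.26 in those 2 alternatives. In macrophage-like cells edgeR passed 0 of 11199 genes, with 1048 at unadjusted p < 0.05 and 188 passed by DESeq2. There 21 list genes passed adjusted over the list alone.

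Seminal vesicle secretion genes were among the largest falls in distal luminal-like, basal-like and fibroblast-like cells. Svs5 (ENSMUSG00000017004, chromosome 2, 164332740 to 164334396) encodes an abundant protein of seminal fluid and changed by log2 −11.22 ± 0.89 in distal luminal-like cells (adjusted p = 7.08e-05) and by −12.64 ± 1.61 in fibroblast-like cells (2.95e-12). In basal-like cells it had no count with collagenase and was at least 1220-fold lower. Svs2, which had 1 count with collagenase in distal luminal-like cells, had a ratio of 7.68e-05 (1.94e-06 to 0.000428), and Svs4 changed there by −10.33 ± 2.02 (0.0161). Seminal vesicle-like cells held these genes in the cold-protease libraries, at 293000 and 201000 CPM of Svs5. The other classes of those libraries held them as well, at 1510 and 4840 in basal-like cells. The 10 secretion genes summed to 14.2, 77.3, 13.2 and 5.6% of the whole-library level in fibroblast-like cells of the 4 libraries, and to 14.3, 59.4, 10.4 and 10.1% in basal-like cells. Cold protease 2 thus carried the most secretory RNA in its fibroblast-like cells, where the fibroblast marker Dcn stood at 1780 CPM against 12100, 12500 and 11200 in the other libraries. The neuronal genes Sncg, Nefl and Tubb3 led the rises in fibroblast-like cells, at least 75.2-fold, 59.8-fold and 56.1-fold, and 5 cells held 98.2, 98.8 and 94.3% of their UMIs. Early-response genes also led in smaller classes: Egr1 rose by 7.79 ± 0.64 in proximal luminal-like cells (0.000627, 154 genes passed). Fosb was at least 50.1-fold higher in T or NK-like cells (41 genes) and 35.1-fold in B or plasma-like cells (76). Fos went from 3 to 1261 counts in endothelial-like cells (128 genes).

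Between the library labelled CD326-depleted and unsorted cold protease, Msmb and Wfdc3 rose and Atf5 fell in distal luminal-like cells, while few genes passed in basal-like and fibroblast-like cells. Msmb (ENSMUSG00000021907, chromosome 14, 32142023 to 32158370), which encodes a prostatic secretory protein, rose from 1950 and 1050 to 11800 CPM, and the protease-inhibitor family gene Wfdc3 from 128 and 164 to 1540. The stress-response factor Atf5 fell from 47.5 and 84.9 to 5.25. Epcam RNA within these cells did not pass the test, but the sort acts on the surface protein, so this does not settle whether cells were depleted. Mouse and sort cannot be told apart, so no direction here can be read as that of a depletion. In distal luminal-like cells 788 of 15468 genes passed, 459 higher and 329 lower.

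The class I MHC gene H2-Q10 rose by log2 3.61 ± 0.32 (adjusted p = 0.0015), and Wfdc3 by 3.39 ± 0.36 (0.003). Msmb rose by 2.97 ± 0.44 (0.00633) and the lipid carrier gene Apoe by 2.94 ± 0.36 (0.00353) in distal luminal-like cells. Atf5 fell by 3.66 ± 0.44 (0.00332), the fucosyltransferase gene Fut9 by 2.85 ± 0.39 (0.00492), the inflammasome-family gene Nlrp10 by 2.81 ± 0.41 (0.00617) and the homeobox gene Hoxb9 by 2.78 ± 0.33 (0.00332). Cluster 12, led by Msmb, Defb50, Wfdc3 and H2-Q10, held 990 cells of this library and 99, 3 and 32 of the others, while cluster 16, led by Defb50, Msmb, Pcp4 and Wfdc3, held 783 cells of cold protease 2 and 30 of this library. Distal luminal-like cells lay mostly in other clusters per library, to 45.7% in cluster 4 here, 47.9% in cluster 7 in cold protease 1 and 52.2% in cluster 0 in cold protease 2. Fut9 was a leading gene of cluster 0 and Nlrp10 of cluster 2, with 8675 of 8777 and 3150 of 3251 cells from cold protease 2, so a different mix of luminal subtypes is not told from a change within cells. Of 18 early-response genes 3 fell and 15 did not pass, the same adjusted over the list alone. Those that fell were Egr1 by 1.99 (0.0191), Atf3 by 1.66 and Fos by 1.57. Among heat-shock genes 1 of 13 fell (1 alone), Hspa1b by 2.57 ± 0.32 (0.0037). Among steroid genes 1 of 11 fell (1 alone), Esr1 by 1.57 ± 0.29 (0.0149). Androgen-responsive genes gave 2 higher and 2 lower of 10 (2 and 2 alone), with Fkbp5 up by 1.57 and the protease gene Tmprss2 down by 1.36. Wnt genes gave 2 higher and 1 lower of 15 (2 and 1 alone). Wnt4 rose by 2.46 ± 0.29 (0.00332), the Wnt antagonist Sfrp1 by 2.43 ± 0.48 (0.0192), and the stem-cell receptor Lgr5 fell by 1.43 (0.0416).

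Most genes of the remaining lists did not pass in distal luminal-like cells. FGF, IGF, HGF and EGF genes gave 1 higher and 2 lower of 22 (1 and 2 adjusted over the list alone), with Igfbp5 down by 2.28 and the HGF receptor Met by 1.36. BMP and TGF-beta genes gave 1 higher of 12 (1 alone), Tgfb1 by 1.77. Hedgehog genes gave 0 of 6 (0 alone), and Notch genes 1 lower of 10 (1 alone), Hey1 by 2.46. Basement membrane genes gave 1 lower of 17 (3 higher and 2 lower alone), the collagen IV chain Col4a6 by 1.90. Fibrillar matrix genes gave 1 higher of 21 (1 alone), Sparc by 1.34. Chemokine genes gave 2 higher of 19 (4 and 1 alone), Cxcl10 by 2.28 and Cxcl17 by 1.85. Complement and interferon genes gave 0 of 12 and 0 of 13 (1 higher alone in each). At unadjusted p < 0.05 these 3 lists without a passed gene had 1 hedgehog, 6 complement and 3 interferon genes, and DESeq2 passed 0 in each. DESeq2 also passed 0 BMP and TGF-beta and 0 fibrillar matrix genes, where edgeR passed 1 each. In basal-like cells 40 of 12278 genes passed, 4 higher and 36 lower, among them Svs5 down by 2.92 ± 0.63 (0.00192). There 0 of 168 list genes passed by edgeR or adjusted over the list alone. In fibroblast-like cells 18 of 11772 passed, 6 higher and 12 lower, with the haemoglobin gene Hbb-bs up by 4.05 ± 0.78 (0.000432). Svs5 stood at 512 CPM in basal-like cells of the library labelled CD326-depleted, against 1510 and 4840 in the unsorted libraries. Seminal vesicle-like cells made up 0.574% of that library, against 3.95 and 5%. A change of Svs5 within basal-like cells is thus not told from less RNA of seminal vesicle-like cells. All 1229 Hbb-bs UMIs of fibroblast-like cells in that library lay in 4 of 1224 cells. The Hbb-bs rise is therefore no change of that class. There 0 of 195 list genes passed either way. In both classes 4 list genes had unadjusted p < 0.05, and DESeq2 passed 0. These counts fell to 0 in basal-like cells thinned to 1000 UMIs (213 at unadjusted p < 0.05) and in fibroblast-like cells without doublet removal (81) or with each library clustered alone (120), and DESeq2 passed 3 genes in each class. Macrophage-like and T or NK-like cells gave 0 genes by edgeR, with 73 and 112 at unadjusted p < 0.05 and 5 and 0 by DESeq2. In proximal luminal-like cells 9 genes passed, among them the mucosal-repair gene Tff3, with 3 counts in the unsorted mice and 1257 here. In seminal vesicle-like cells 88 passed, with Sva, a seminal fluid gene, at least 4.28-fold lower, but DESeq2 passed 2. Sva was a leading gene of cluster 20, with 689 of 695 cells from cold protease 2, while 97.7% of the class here lay in cluster 17. A different mix of clusters is thus not told from a change within these cells. In B or plasma-like cells 4 passed, with the immunoglobulin gene Iglc2 up by 5.40 ± 0.70 (3.33e-11).

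Fibroblast-like cells carried more of the growth factor Igf1, complement C3 and the chemokine Cxcl13 than smooth muscle-like cells, which carried more of the Notch feedback gene Nrarp. Igf1 (ENSMUSG00000020053, chromosome 10, 87858265 to 87937042) stood at 1100 against 27 CPM and C3 (ENSMUSG00000024164, chromosome 17, 57203970 to 57228136) at 748 against 21.1, as means of 3 libraries with at least 20 cells of both classes. The oestrogen sulfotransferase gene Sult1e1, which inactivates oestrogens, stood at 1430 against 4.23. Each library entered as a block, and 48 of 166 list genes passed, 43 higher and 5 lower, or 71 adjusted over the list alone, among 477 of 7503 genes. The count rested on cold protease 2: without it 0 of 181 list genes passed by edgeR, with 73 at unadjusted p < 0.05, where DESeq2 with all libraries passed 54. Without the collagenase library 84 passed, and without a library block 19.

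Igf1 was higher in fibroblast-like cells by log2 5.79 ± 0.82 (adjusted p = 0.00881), C3 by 5.79 ± 0.83 (0.00894), Sult1e1 by 8.22 ± 0.65 (0.00157) and the elastic-fibre gene Efemp1 by 4.97 ± 0.58 (0.00407). The B-cell attractant Cxcl13 had 6329 counts in fibroblast-like and 1 in smooth muscle-like cells, the eosinophil attractant Ccl11 had 2162 and 3, and the IGF carrier Igfbp3 was at least 22.8-fold higher. Complement gave 7 higher of 11 (7 adjusted over the list alone), and fibrillar matrix 7 of 21 (13). Chemokines gave 6 of 12 (6), basement membrane 5 higher and 1 lower of 14 (5 and 1). FGF, IGF, HGF and EGF genes gave 4 of 14 (8 and 1), with Egfr up by 3.32 and the epithelial growth factor Fgf10 by 2.61. Steroid genes gave 3 of 8 (4), Wnt genes 3 of 15 (5), and interferon genes 3 of 7 (5). BMP and TGF-beta genes gave 3 higher and 1 lower of 12 (4 and 1), androgen-responsive genes 1 of 9 (2) and immediate-early genes 1 of 18 (6). Heat-shock genes gave 1 lower of 13 (1), Notch genes 2 lower of 8 (2) and hedgehog genes 0 of 4 (0, with 0 at unadjusted p < 0.05 by edgeR and 0 by DESeq2). DESeq2 also passed 0 androgen-responsive genes. Nrarp was lower by log2 −5.24 ± 0.87 (0.0148) and Tgfb3 by −2.39. Fgf7, at 2.13, Wnt2, at 3.07, and the 5-alpha-reductase gene Srd5a2, at 2.83, did not pass.

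Basal-like cells carried more Lamb3, hedgehog ligand Shh and Notch ligand Jag2, and distal luminal-like cells carried more Epcam and oestrogen receptor. Shh (ENSMUSG00000002633, chromosome 5, 28456815 to 28467256) stood at 27.7 against 0.968 CPM (means of 4 libraries), the laminin chain Lamb3 at 72 against 2.46, and the keratinocyte growth factor receptor Fgfr2 at 71.9 against 5.18. Epcam was lower in basal-like cells by −1.25 ± 0.20 (adjusted p = 0.000329). Of 192 list genes 122 passed, 92 higher and 30 lower, or 127 adjusted over the list alone, among 6443 of 14596 genes. Luminal secretory RNA was present in basal-like cells too, most in cold protease 2. Without a library block 79 list genes passed.

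Shh was higher in basal-like cells by log2 4.84 ± 0.29 (adjusted p = 1.1e-06), Lamb3 by 5.0 ± 0.31 (1.1e-06), and the Notch ligand Jag2 by 4.68 ± 0.37 (1.88e-06). So were the 5-alpha-reductase gene Srd5a1 by 4.36 ± 0.28 (1.1e-06) and the alarmin Il33 by 5.37 ± 0.43 (1.99e-06). Basement membrane genes gave 14 higher and 1 lower of 17 (14 and 1 adjusted over the list alone), BMP and TGF-beta genes 9 and 1 of 14 (9 and 1), with Bmp4 up by 4.90. Growth factor genes (FGF, IGF, HGF and EGF) gave 9 and 3 of 20 (10 and 3). Hedgehog genes gave 3 and 1 of 5 (3 and 1), with Gli3 up by 4.65 and Smo by 3.38. Notch genes gave 4 and 1 of 9 (5 and 1), and Wnt genes 6 and 2 of 14 (7 and 2), with Lgr5 lower by −1.77. Chemokine genes gave 9 and 2 of 17 (9 and 2), fibrillar matrix 9 and 2 of 20 (9 and 2), complement 3 and 4 of 12 (3 and 4) and interferon genes 5 and 4 of 13 (5 and 4). Steroid genes gave 4 and 3 of 10 (4 and 3), with the mineralocorticoid receptor Nr3c2 lower by −3.41 and Esr1 by −1.20 ± 0.26 (0.00226). Androgen-responsive genes gave 4 and 4 of 10 (4 and 4), with Ndrg1 up by 4.99 and Tmprss2 lower by −2.88. Immediate-early genes gave 8 and 0 of 18 (9 and 0) and heat-shock genes 5 and 2 of 13 (5 and 3).

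Proximal luminal-like cells, which line the ducts near the urethra, carried more Wnt4, Ihh, Fgfr3 and secreted chaperone clusterin (Clu) than distal luminal-like cells. Wnt4 stood at 245 against 18.4 CPM, Clu at 4340 against 101 and the growth factor receptor Fgfr3 (ENSMUSG00000054252, chromosome 5, 33721674 to 33737068) at 50.6 against 0.58. Esr1 and Lgr5 were lower in them, and Epcam was higher by 0.69 ± 0.17 (adjusted p = 0.0104). Of 178 list genes 82 passed, 60 higher and 22 lower, or 84 adjusted over the list alone, among 5019 of 13664 genes. The collagenase library gave only 27 proximal luminal-like cells, and without a library block 46 list genes passed.

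Fgfr3 was higher by log2 6.40 ± 0.31 (adjusted p = 2.31e-06), Ihh by 5.17 ± 0.30 (4.89e-06), and the lung-type chemokine gene Cxcl15 by 5.90 ± 0.43 (1.67e-05). So were Clu by 5.10 ± 0.54 (0.000114) and Wnt4 by 3.99 ± 0.35 (4.34e-05). Esr1 was lower by −1.93 ± 0.21 (0.000134), Bmp7 by −2.71 ± 0.25 (5.63e-05) and Lgr5 by −2.36 ± 0.61 (0.014). FGF, IGF, HGF and EGF genes gave 9 higher and 0 lower of 20 (9 and 0 adjusted over the list alone), with the EGF-receptor ligand Areg up by 5.36 in 3 of 4 libraries. Interferon genes gave 7 and 0 of 13 (7 and 0), with the antiviral gene Oasl2 up by 3.01, and hedgehog genes 4 and 0 of 5 (4 and 0). Notch genes gave 5 and 1 of 8 (5 and 1), BMP and TGF-beta genes 5 and 3 of 10 (6 and 3), and Wnt genes 5 and 3 of 13 (5 and 3). Basement membrane genes gave 6 and 1 of 16 (6 and 1) and chemokines 5 and 1 of 17 (6 and 1). Immediate-early genes gave 5 and 1 of 18 (5 and 1), complement 3 and 1 of 11 (3 and 1), and androgen-responsive genes 2 and 2 of 10 (2 and 2). Steroid genes gave 1 and 2 of 9 (1 and 2), fibrillar matrix 1 and 1 of 15 (1 and 1), and heat-shock genes 2 and 6 of 13 (2 and 6), with Hsph1 lower by −1.94.

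The 2994 fibroblast-like cells parted into 12 subclusters. The 3 tested were a Sult1e1, C3 and Igf1 group (995 cells), a Wnt2 and Srd5a2 group (343) and an Lgr5 and Cxcl12 group (319). Wnt2 (ENSMUSG00000010797, chromosome 6, 17988940 to 18030585), a secreted signal for epithelium, stood at 772 against 85.7 CPM in subcluster 1 and the other fibroblast-like cells, and Srd5a2 (ENSMUSG00000038541, chromosome 17, 74016955 to 74047916), which makes dihydrotestosterone, at 393 against 32.4. Lgr5 (ENSMUSG00000020140, chromosome 10, 115450311 to 115587780), a receptor that boosts Wnt signals, stood at 572 against 36.9 in subcluster 3, with the chemokine Cxcl12 at 1880 against 268. Igf1 stood at 2140 against 783 in subcluster 0. Of 12 subclusters these 3 had at least 20 cells in at least 3 libraries, and subclusters 2, 4, 6 and 8 came almost wholly from the collagenase library (310 of 321, 286 of 287, 143 of 170 and 93 of 93 cells). The collagenase library gave 64, 20 and 22 of its 961 fibroblast-like cells to subclusters 0, 1 and 3. Subcluster 4 shared the leading genes Rorb and Gm48898 with subcluster 1, and its cells counted among the others in that comparison.

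In subcluster 1, led by Adm, Rorb and the Wnt inhibitor Notum, Wnt2 was higher by log2 3.22 ± 0.36 (adjusted p = 4.11e-06), and Srd5a2 by 3.71 ± 0.38 (1.7e-06). So were Wnt10a by 3.73 ± 0.32 (2.91e-07) and the BMP antagonist Nog by 3.83 ± 0.69 (0.000646). Lgr5 was lower there by −5.12 ± 0.48 (7.41e-07), C3 by −5.50 ± 0.45 (1.56e-07), the adhesion protein gene Fn1 by −5.93 ± 0.38 (1.38e-08) and, in 3 of 4 libraries, Fgf10 by −1.45. Periostin (Postn) was at least 28.9-fold lower. In all 92 of 164 list genes passed, 26 higher and 66 lower, or 100 adjusted over the list alone. They were among 978 of 7280 genes, and 34 without a library block. Fibrillar matrix gave 1 higher and 14 lower of 21 (1 and 14 adjusted over the list alone), complement 1 and 8 of 11 (1 and 9), and chemokines 5 and 8 of 15 (5 and 8). Wnt genes gave 7 and 3 of 14 (7 and 3), BMP and TGF-beta genes 4 and 5 of 13 (6 and 6) and FGF, IGF, HGF and EGF genes 4 and 6 of 15 (4 and 8). Interferon genes gave 0 and 5 of 8 (0 and 5), basement membrane genes 2 and 4 of 13 (2 and 4), and steroid genes 1 and 2 of 7 (1 and 3). Androgen-responsive genes gave 0 and 3 of 9 (0 and 3), immediate-early genes 1 and 7 of 18 (1 and 7), heat-shock genes 0 and 1 of 13 (0 and 2), and hedgehog and Notch genes 0 of 4 and 3 (0 alone in both, with 0 at unadjusted p < 0.05 by edgeR and 0 by DESeq2).

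In subcluster 3, led by Pdlim3 and Osr1, Lgr5 was higher by 4.17 ± 0.30 (adjusted p = 9.72e-15), and Cxcl12 by 2.87 ± 0.17 (5.94e-17). So were elastin (Eln) by 2.94 ± 0.31 (8.05e-10), the epithelial growth factor Fgf7 by 2.10 ± 0.26 (4.93e-08) and, in 2 of 3 libraries, the hedgehog-binding gene Hhip by 2.12 ± 0.37 (4.24e-05). Igf1 was lower by −3.12 ± 0.21 (1.05e-15), C3 by −3.97 ± 0.24 (1.19e-16) and Srd5a2 by −1.70 ± 0.33 (0.000166), while Wnt2, at −0.43, did not pass. In all 71 of 164 list genes passed, 15 higher and 56 lower, or 88 adjusted over the list alone. They were among 812 of 8265 genes, against 47 without the library labelled CD326-depleted and 8 without a library block. FGF, IGF, HGF and EGF genes gave 1 and 9 of 15 (2 and 10 adjusted over the list alone), fibrillar matrix 2 and 9 of 21 (2 and 12), and immediate-early genes 0 and 8 of 17 (0 and 9). Complement gave 2 and 5 of 11 (2 and 7), chemokines 1 and 5 of 11 (1 and 6) and basement membrane genes 2 and 5 of 14 (2 and 5). Steroid genes gave 0 and 4 of 8 (1 and 5), Wnt genes 2 and 4 of 15 (2 and 4), and BMP and TGF-beta genes 3 and 3 of 11 (3 and 3). Androgen-responsive genes gave 0 and 2 of 9 (0 and 3), hedgehog genes 1 and 0 of 5 (3 and 0), heat-shock genes 1 and 1 of 13 (2 and 2), interferon genes 0 and 1 of 11 (0 and 1) and Notch genes 0 of 3 (0 and 1, with 1 at unadjusted p < 0.05 by edgeR and 0 by DESeq2). DESeq2 passed 42 list genes, and 0 of the heat-shock, androgen-responsive, hedgehog and interferon lists.

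In subcluster 0, led by Gpx3 and Inmt, Sult1e1 was higher by 2.64 ± 0.38 (adjusted p = 0.000779), and C3 by 1.66 ± 0.22 (0.000504). So were Igf1 by 1.61 ± 0.27 (0.00206), Egfr by 1.50 ± 0.23 (0.00122) and, in 3 of 4 libraries, Fgf10 by 1.37 ± 0.37 (0.0409). The Wnt inhibitor gene Wif1 was lower by −5.95 ± 0.37 (1.38e-06), Srd5a2 by −5.07 ± 0.44 (1.74e-05), Wnt2 by −4.44 ± 0.37 (1.37e-05) and, in 3 of 4 libraries, Lgr5 by −1.50 ± 0.35 (0.0166). The secretory genes Svs4, Spink1 and Sbp, which other classes of the cold-protease libraries held too, were also among its leading genes. In all 46 of 153 list genes passed, 22 higher and 24 lower, or 66 adjusted over the list alone, among 438 of 6237 genes. Only 25 passed without the library labelled CD326-depleted, 29 without cold protease 1 and 5 without a library block, but 70 without the collagenase library. Wnt genes gave 1 and 8 of 13 (1 and 9 adjusted over the list alone), fibrillar matrix 4 and 2 of 21 (7 and 4), chemokines 3 and 3 of 13 (5 and 3), and complement 3 and 2 of 11 (5 and 2). FGF, IGF, HGF and EGF genes gave 3 and 2 of 13 (3 and 3), basement membrane genes 3 and 1 of 12 (3 and 2) and BMP and TGF-beta genes 0 and 3 of 11 (3 and 3). Immediate-early genes gave 2 and 0 of 18 (4 and 0), androgen-responsive genes 2 and 0 of 9 (2 and 0), and steroid genes 1 and 1 of 7 (1 and 1). Hedgehog genes gave 0 and 1 of 3 (0 and 2), interferon genes 0 and 1 of 7 (0 and 2), heat-shock genes 0 of 13 (1 and 0) and Notch genes 0 of 2 (0 alone). In the 2 lists without a passed gene 1 heat-shock and 0 Notch genes had unadjusted p < 0.05 by edgeR, and DESeq2 passed 0. DESeq2 also passed 0 interferon genes, and 37 list genes in all.

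**Figure D4:**
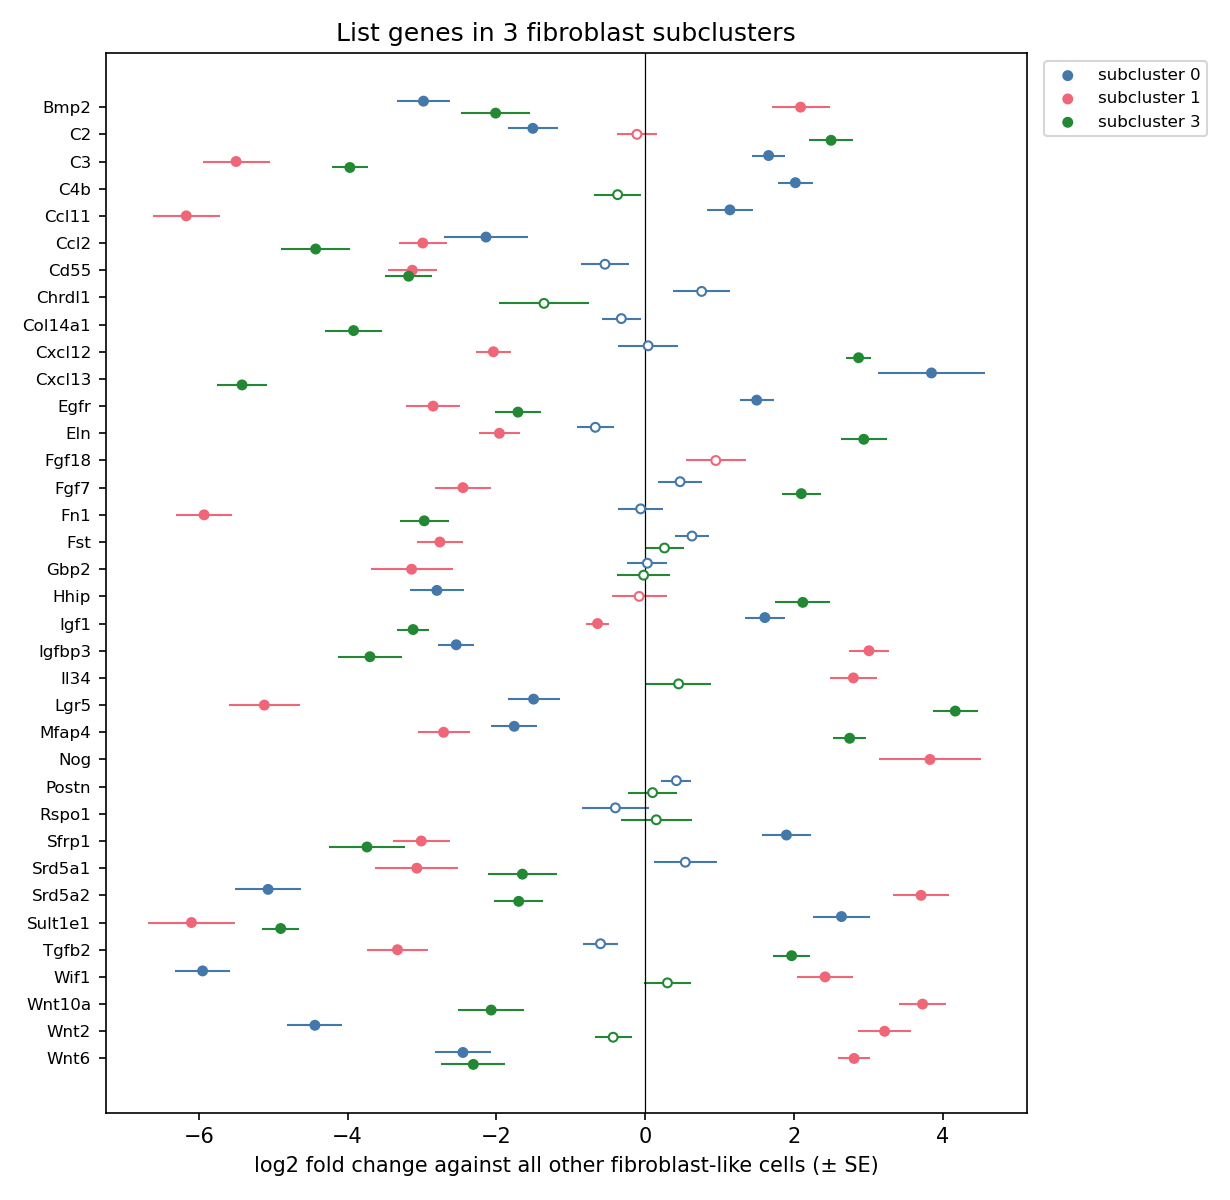
Log2 fold change (± SE) of list genes in fibroblast subclusters 0, 1 and 3 against all other fibroblast-like cells, with open circles for genes that did not pass and genes with at most 3 counts on 1 side not drawn. Lgr5 lies at −1.50, −5.12 and 4.17 in subclusters 0, 1 and 3, and C3 at 1.66, −5.50 and −3.97.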

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

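The tests of the Epcam label, of the seminal vesicle genes, of depth in basal-like and fibroblast-like cells and of the kit bias for the remaining early-response genes were chosen after the result was seen; those on depth in distal luminal-like cells, mitochondrial share, kit bias as a whole and other splits of the samples were set before.

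Epcam RNA in the library labelled CD326-depleted was as high as in the unsorted cold-protease libraries. Free Epcam RNA is argued against, since Epcam in its distal luminal-like cells was 7.26 times that in its fibroblast-like cells (lower 95% bound 6.08). A swap with an unsorted cold-protease library was not decided. Their epithelial shares, 83.4 and 92.5%, were both above the 77.8% found here, so neither looked depleted. The pair itself spread by an SD of 6.43 (n = 2), so these shares cannot exclude a swap. A depletion that spared cells with little Epcam RNA may remain: 0 of 3 epithelial classes had less Epcam RNA than in both unsorted libraries, but basal-like cells per distal luminal-like cell rose to 1.13. Difference between mice, a wrong label and a partial sort cannot be told apart with 1 library, and no biological explanation was tested.

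Immediate-early genes were higher in the collagenase library. In distal luminal-like cells 17 genes still rose with cells thinned to 1000 UMIs, which decides nothing on depth, since these cells had 5176.5 UMIs with collagenase (median) against 8306 and 4964. Basal-like and fibroblast-like cells had 6365 and 6933 UMIs with collagenase against at most 3023.5 and 1972. At least 88.2% of the genes still rose there when thinned. The sums were rescaled to a common total with and without thinning, so large rises would stay in either case. This result therefore decides nothing on depth in these classes. In distal luminal-like cells 17 genes still rose with at most 10% mitochondrial UMIs, so kept cells above that share are argued against as the whole cause. Barcodes above 20% had already been removed, and a low share does not show a cell to be undamaged. Damage itself was therefore not decided. A fixed bias of the newer kit per gene is argued against as the whole cause for 4 genes (Atf3, Nr4a1, Zfp36 and Myc). Their effect differed between classes, adjusted over the list alone, in a test with 1 residual degree of freedom. For the 14 other genes such a bias stays open. For these 4 and the 14 others alike, the kit, the mouse and a response to collagenase digestion cannot be told apart, since all 3 changed together.

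Seminal vesicle secretion genes were lower in the collagenase library in distal luminal-like, basal-like and fibroblast-like cells. Free RNA of seminal vesicle cells is compatible with the values of the unsorted cold-protease libraries. The Svs5 to Svs4 ratio varied at most 1.21 times between distal luminal-like, basal-like and fibroblast-like cells of the same library. That test leaves out the source. Seminal vesicle-like cells held Svs5 and Svs4 at 293000 and 11600 CPM in cold protease 1, and at 201000 and 95100 in cold protease 2. Basal-like cells held 1510 and 67.6, and 4840 and 2650, in similar proportion. The proportions were unlike in the library labelled CD326-depleted, with 271000 and 6520 against 512 and 90.4. A loss of all secretory RNA alike is argued against, since the lowest of the Pbsn, Tgm4 and Msmb ratios to cold protease was 0.791 in distal luminal-like cells. A loss of part of it stays open: Spink1 stood at 11500 CPM there against 96200 and 66900, and Defb50 at 3130 against 11700 and 8890. Whether seminal vesicle tissue was left out of the collagenase dissection was not tested.

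Differences of effect between fibroblast-like and distal luminal-like cells (an interaction test in edgeR, 1 residual degree of freedom) drew attention to 13 genes, given as values without a weighing. For collagenase, the log2 effect in fibroblast-like cells minus that in distal luminal-like cells was −2.88 ± 0.76 for Wnt6, 3.05 ± 0.62 for Col6a3, −2.63 ± 0.59 for Wnt4, 2.68 ± 0.64 for Zfp36, 2.28 ± 0.64 for Ccl11, −2.99 ± 0.77 for Bmp4, 2.31 ± 0.61 for Myc and 2.38 ± 0.67 for Ifit1. For the library labelled CD326-depleted it was −3.25 ± 0.61 for Col4a1, −2.87 ± 0.62 for Sfrp1, 2.36 ± 0.57 for Lgr5, 2.74 ± 0.60 for C2 and 2.61 ± 0.62 for Hspa1b. The unnamed cluster 9, used in no class, held 27.2% of collagenase cells and 0.0125 to 0.45% of the others.

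Other splits of the library sums were counted for the class contrasts. Both sums of a library come from 1 mouse, so the real split is set against the splits that part every library's pair, of which there are 8, or 4 for fibroblast-like against smooth muscle-like cells and subcluster 3. In each of the 6 contrasts 1 of them, the real one, was as large, and these splits are too few for a share under 0.05. The classes and subclusters also came from clustering these same cells, on genes that can vary with the list genes. A higher count for the real split was thus likely beforehand, and the p-values of these contrasts carry the same limit. The real split gave 48 list genes for fibroblast-like against smooth muscle-like cells, 122 for basal-like and 82 for proximal luminal-like against distal luminal-like cells, and 46, 92 and 71 for subclusters 0, 1 and 3, and the highest other gave 0 in each. Splits that leave pairs together set sums of different mice against each other; 32 splits of this wider kind could be fitted and 3 could not in the contrasts with 4 libraries, with a highest other of 15 for subcluster 0.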

How the results depend on the processing

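Counting cluster 9 as distal luminal-like and leaving out 3 fibroblast subclusters were chosen after the result was seen; the other alternatives were planned. Of counts, shares and named gene values under the alternatives, 6415 were labelled the same, 665 weaker, 135 stronger, 92 moved and 5 reversed. For a tested gene, the same means that it passed or did not pass as before, not that its size was unchanged. The cause was not tested in any of the cases given here.

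Collagenase against cold protease passed 1115 genes in distal luminal-like cells, and 1899 without doublet removal, 2104 at Leiden resolution 2 and 2258 without a count filter. It passed 602 in basal-like cells, and 954 with each library clustered alone, 131 thinned and 348 with DESeq2. Most of the 602 were not among the 954, nor among the genes that passed with the stricter filter. The count of 394 in fibroblast-like cells became 0 in edgeR without doublet removal and 0 with each library clustered alone (822 and 862 at unadjusted p < 0.05). It became 245 thinned and 131 with DESeq2, not all of them among the 394. Prior degrees of freedom of edgeR were infinite at 394 genes, and 5.84 and 6.26 at those counts of 0. For the library labelled CD326-depleted, 788 in distal luminal-like cells became 1338, 1632 and 1869 without doublet removal, at resolution 2 and without a count filter, and 451 thinned. There 40 in basal-like cells became 14 with the stricter filter, 19 at 10% mitochondrial UMIs, 0 thinned (edgeR, 213 at unadjusted p < 0.05) and 3 with DESeq2, and 18 in fibroblast-like cells became 0 without doublet removal, 0 with each library alone (edgeR, 81 and 120 at unadjusted p < 0.05) and 3 with DESeq2. Leaving out either cold-protease mouse gave values with no test.

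Fibroblast-like against smooth muscle-like cells passed 48 list genes, 81 with the stricter filter, 90 without a count filter and 19 without a library block, and leaving out 1 library gave 0 (edgeR, without cold protease 2, 73 at unadjusted p < 0.05; DESeq2 with all libraries 54) to 84. Without a block 122 became 79 for basal-like, 82 became 46 for proximal luminal-like cells, and 46, 92 and 71 became 5, 34 and 8 for subclusters 0, 1 and 3. Subcluster 0 gave 73 without doublet removal, 78 without centring and 25 to 70 with 1 library left out. Subcluster 3 gave 42 with DESeq2 and 47 to 70 with 1 library left out; without centring its match (Jaccard index 0.759) had too few cells outside 1 library to test.

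Epithelial shares moved to 85.4 and 85.9% in cold protease 2 (10% mitochondrial UMIs, resolution 2), to 78.7, 78.7 and 74.1% in the library labelled CD326-depleted (stricter, 10% mitochondrial, no doublet removal) and to 69, 42.9, 47.9 and 73.4% in the collagenase library (stricter, no doublet removal, resolution 2, cluster 9 counted). Basal-like shares moved to 40.9, 41.1 and 37.9% in the library labelled CD326-depleted under the same 3 settings, and to 9.33% (stricter) and 7.21% (each alone) with collagenase, where fibroblast-like cells became 11.1% (stricter). Thinning moved cells with an Epcam UMI to 20.1, 20.8, 19.7 and 31.8%.

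Srd5a2 in fibroblast-like cells with collagenase reversed to −4.41 ± 0.90 (adjusted p = 8.43e-05) with the stricter filter. In subcluster 0 Ccl2 reversed to 0.12 (stricter) and 2.24 (no doublet removal), and Irf7 to 0.81 and Epcam to −1.46 without doublet removal. In the simulations, log2 1 changes were recovered to 0 to 6.06% in group comparisons and 0 to 57.4% in class contrasts, so most small differences between groups would be missed.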

Other observations

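Cold protease 2 gave 27431 barcodes, 158% of the number of cells to be loaded, where the others gave 41.3, 101 and 52%. Ionocyte-like cells (Foxi1, Atp6v1g3), a rare ion-transporting type, made up 1.8 and 0.561% of the unsorted cold-protease libraries and held Svs5 at 64100 and 32900 CPM, against 952 and 2560 in distal luminal-like cells of the same libraries. A fibroblast subcluster of 76 cells was led by the neuronal genes Sncg, Prph and Nefl, but most of its cells lacked Sncg and Nefl. Fibroblast-like cells of cold protease 2, with 29 cells there, had 0 UMIs of both genes, and those of the library labelled CD326-depleted, with 43, had 3 of each, while 5 collagenase cells held 98.2 and 98.8% of those in the collagenase library. A subcluster of 249 cells led by Krtdap, haemoglobin genes (Hba-a1, Hba-a2, Hbb-bs, Hbb-bt) and the adventitial marker Pi16 came mostly (187 cells) from the library labelled CD326-depleted. All Hba-a1, Hba-a2 and Hbb-bs UMIs of fibroblast-like cells in that library lay in 3, 2 and 4 cells, so most of its cells lacked them.

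Clusters in which more than 80% of cells came from 1 library held 0, 89.6, 44.7 and 83.2% of cells of the 4 libraries. Ribosomal protein genes took 25.7, 29.6, 17.9 and 20.8% of UMIs. The rRNA-overlapping transcript Gm42418 stood at 26200 CPM in the collagenase library and at 256, 66 and 461 in the others.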
